A study of Mus musculus with 3 samples.

How the data were processed

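Total RNA of CD8+ T cells was measured on 3 Agilent mouse arrays in 1 colour (Cy3), with 1 array per group. Per the labels, the cells carried the pmel-1 T cell receptor, a transgenic receptor for the melanocyte antigen gp100. The naive array held naive cells taken from pmel-1 spleen by magnetic separation. The peptide and DC arrays held pmel-1 cells sorted from the spleens of mice that had received pmel-1 splenocytes and then a short gp100 peptide vaccine or a dendritic cell (DC) vaccine on days 0 and 14, with the sort on day 28. Labelled RNA was made from 0.1 µg of total RNA, per the labels' protocols.

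The authors deposited 1 scanner file per array and 1 table of processed values. Per the file headers and the submitters' processing notes, spot intensity was extracted with Agilent Feature Extraction 11.5.1.1. Per the file headers, the processed signal is an intensity on a linear scale after background subtraction and detrending within each array, with no normalization between arrays. The deposited table of processed values is on a log2 scale. Its scale, centring and floor are not given in the sources used here and were read from the values. Among 20068 probes with a mean log2 signal over 6, its differences between arrays were within 0.02 of those from the scanner files for 99.4% of probes (peptide minus naive), 99.3% (DC minus naive) and 99.6% (DC minus peptide). It was therefore read as log2 of the processed signal, shifted by each array's 75th percentile and centred per probe on the 3 arrays. The median of each of its 3 columns was 0, and 23.8% of probes stood at 0 on all arrays. The direction of its differences is that of the scanner files. How its floor was set stays unknown.

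For the main values, spots with a non-uniformity or population outlier mark were left out (165 on the naive, 209 on the peptide and 170 on the DC array), spots of the same probe were averaged on the log2 scale, and each array's 75th percentile of log2 processed signal over the non-control probes was subtracted. Control spots were left out, and no spot was saturated on any array. Of 55681 non-control probes, 28331 were named through their transcript accession in the RefSeq gene table of assembly GRCm38.p6, which gave 21368 genes, of which 21367 had a value on all arrays. Of 26732 probes with a RefSeq mRNA accession, 26469 were named. The other 27350 of all probes had no name there and entered the scaling alone. The probe with the highest mean over the arrays stood for its gene. For 22 genes on the naive array, 10 on the peptide array and 20 on the DC array, the chosen probe was not well above background where another probe of the gene was. Among genes with several measured probes, 19 of 3214 (peptide over naive), 20 of 3178 (DC over naive) and 4 of 3242 (DC over peptide) had 1 probe at least 2-fold higher and another at least 2-fold lower.

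A gene was measured on an array where Feature Extraction marked its probe as well above background. Where only 1 array of a pair measured a gene, the dim side was set to the higher of the lowest signal among well-above-background probes on that array and the probe's own signal, and the difference is given as a bound ("at least"). No fold is given where both were below background. The comparisons were peptide over naive, DC over naive and DC over peptide, each a difference of scaled log2 values. With 1 array per group there are no replicates, so no test between groups was run, no p-value is given, and the number of arrays limits the precision of every value. The spread of a measurement within an array was taken from probes printed as 10 spots. The naive array lay on 1 slide and scan, and the peptide and DC arrays shared another, so slide and scan cannot be told apart from the difference between naive and vaccine-primed cells.

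Lists of genes were fixed, with the rule for named genes, before the data were examined, as were the main values, the comparisons and 8 alternatives. The 29 lists held 512 genes: CD8 T cell identity, cytotoxic effector molecules, cytokines and chemokines, naive T cell genes, effector and memory transcription factors, antigen-experience markers, killer-cell lectin-like receptors, chemokine receptors and trafficking, inhibitory receptors and exhaustion, costimulation and activation receptors, proliferation, interferon-stimulated genes, apoptosis and survival, glycolysis, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, immediate early genes, heat shock and chaperones, and markers of B cells, plasma cells, CD4 and regulatory T cells, NK cells, macrophages with monocytes and dendritic cells, granulocytes, erythroid cells, platelets, and stromal with endothelial cells. For 13 of the genes no named probe was found, and 6 genes stood in more than 1 list. For each list the median difference of its measured members was set beside 10000 random lists of the same size, matched on mean log2 value in 25 bins. Its percentile among these describes these arrays and is no test.

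The rule for named genes took, per comparison, the 10 genes with the largest positive and the 10 with the largest negative difference measured on both arrays, the 5 per direction with the largest bound, up to 4 members per list with the largest difference together with any member at least 2-fold apart, and a fixed set of T cell genes. Unnamed or predicted transcripts, immunoglobulin and T cell receptor segments and genes whose probes disagreed in direction were passed over in its first 2 parts. The text names a selection of these, and some are not reported here by name, although they count in the lists.

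The alternatives were normexp background correction with an offset of 50 on the median spot signal and local background, quantile normalization, scaling on the median of probes measured on all arrays, no filter on dim probes, a stricter filter on dim probes, the median over a gene's probes, the deposited table of processed values, and leaving out saturated genes. The mean spot signal planned for normexp was not used here, and the median spot signal stood in its place. The stricter filter kept genes measured on both arrays of a pair and, on at least 1 of them, above the median of well-above-background signals. Genes measured on 1 array of the pair were left out by it, however bright. One more alternative, in which the measured difference replaced the bound for genes measured on 1 side, was chosen after seeing the data, as were the lists of Notch target, thymocyte and Y-linked genes in the closing section. Limma 3.58.1 in R 4.3.3 ran normexp. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 ran the rest.

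The calculations were tested on simulated arrays made from the real naive or peptide array with spot noise of 0.07 (log2), an overall factor of 0.8 between arrays and 200 changed genes among 21367 for peptide over naive. All 33 genes lowered by a log2 difference of 1.5 and all 34 raised by as much were called at least 2-fold apart, with medians of -1.51 and 1.52, and 0% of 13162 unchanged genes were. With noise this small and the well-above-background marks copied from 1 array, these calls were nearly fixed in advance. They check the calculation and give no rate of false calls for the real arrays. Among 200 lists of 20 unchanged genes, 4.5% lay outside the central 95% of random lists.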

Results

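Gene expression was measured in pmel-1 CD8+ T cells from 3 sources, with 1 array each: naive cells, cells primed by a short gp100 peptide vaccine and cells primed by a DC vaccine. The study set naive cells against cells primed by either vaccine, and the vaccines against each other. The 75th percentile of processed signal was 322 on the naive, 261 on the peptide and 254 on the DC array. Of 21367 genes, 13340 were well above background on the naive array, 13079 on the peptide array and 13083 on the DC array. There were no replicates. Probes printed as 10 spots had a median SD between spots of 0.064, 0.068 and 0.074 (log2) on the 3 arrays. For a probe of median spread, the 95% half-width was 0.184 for a peptide minus naive difference, 0.191 for DC minus naive and 0.200 for DC minus peptide. Dim probes spread more: their dimmer part had median SDs of 0.091, 0.100 and 0.095, against 0.054, 0.056 and 0.061 for the brighter part. This spread covers spot noise within an array and nothing of the variation between mice.

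In the comparison of peptide-primed with naive cells, genes of the cell cycle were higher on the peptide array, and the lists of interferon-stimulated genes, killer-cell lectin-like receptors and cytotoxic molecules had medians below 0 and below the central 95% of random lists. Mki67, a marker of cycling cells, was 15.2-fold higher. Gzmb and Prf1, which encode granzyme B and perforin, were 5.17-fold and 2.52-fold lower, and Ifng was 6.79-fold higher. The inhibitory receptors Pdcd1 (PD-1) and Ctla4 were higher by log2 differences of 3.34 and 4.53. Of 12250 genes measured on both arrays, 2231 were at least 2-fold higher on the peptide array and 1353 at least 2-fold lower, and a further 741 and 343 were measured on the peptide or the naive array alone with a bound of at least 2-fold.

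All 29 measured proliferation genes were higher on the peptide array, 28 of them at least 2-fold on both arrays and 1 by its bound, with a median log2 difference of 3.70. Bub1b stood at 4.75, Birc5 at 4.78, Rrm2 at 4.62 and Top2a at 4.26. The median lay at percentile 100 of random lists. The metabolic groups with medians above the central 95% of random lists were glycolysis (0.86, with 9 of 20 genes at least 2-fold higher and 2 lower), oxidative phosphorylation (0.87, with 7 of 20 higher) and cholesterol synthesis (0.85, with 8 of 19 higher). Among them were the hexokinase Hk2 (2.96), the sterol enzymes Sqle (2.44) and Cyp51 (2.36), and the cytochrome oxidase subunit Cox6c (1.94), while the pyruvate dehydrogenase kinase Pdk1 was lower (-2.07). Fatty acid oxidation had a median of -0.03 that turned to 0.36 with the stricter filter, and 13 of its 17 genes lay within 2-fold. All 22 ribosomal protein genes lay within 2-fold, with a median of 0.20, below the central 95% of random lists (0.23 to 0.82). The median turned to -0.05 under quantile normalization, and there and without the filter it lay within the central 95%.

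All 26 measured interferon-stimulated genes were lower on the peptide array, 22 of them at least 2-fold on both arrays and Ifi44 by its bound, and the median was -1.93. Ifit3 stood at -5.25, Ifit1 at -4.18 and Oasl1 at -3.44. Killer-cell lectin-like receptors, which NK cells and antigen-experienced CD8 T cells carry, had a median of -2.52 (-2.06, within the central 95% of random lists, with the stricter filter), with 7 of 17 measured on both arrays and at least 2-fold lower and 8 measured on the naive array alone. Those 8 were left out by the stricter filter. Klrd1 was 6.07-fold lower and Klra7 at least 288-fold lower. Markers of NK cells moved with them, with a median of -1.78 (-1.41, within the central 95%, with the stricter filter), and Klra4 and Ncr1 were measured on the naive array alone. Cytotoxic molecules had a median of -0.93. Of 13 measured, 6 were at least 2-fold lower, among them Fasl (-2.47), Serpinb9 (-1.86) and Gzmm (-1.59), and 1 was higher, the granzyme Gzma (5.57, or 47.4-fold).

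Cytokines and chemokines had a median of -0.19, with 5 lower and 2 higher of 13, and of -1.35, below the central 95%, with the stricter filter. The chemokines Ccl5 (-3.50), Ccl4 (-2.16) and Ccl3 (-1.98) were lower, and Ifng (2.76) and Il4 (3.12) were higher. Chemokine receptor and trafficking genes had a median of -0.46: Cxcr6 (-3.92) and Cxcr3 (-3.08) were lower, and Ccr4 (5.63) and Ccr8 (2.26) were higher. On the naive array Ccr8 (scaled log2 -4.69) and Il4 (-4.35) lay near the lowest well-above-background signal (-4.89). The size of their differences is therefore imprecise. Transcription factors of effector and memory cells had a median of 0.73, with 8 of 18 at least 2-fold higher and 6 lower. Bhlhe40 (4.38), Irf4 (4.12), Ikzf2 (3.45) and Nfil3 (3.33) were higher, whereas Eomes (-3.05), Prdm1 (-1.61), Stat4 (-1.38) and Tbx21 (-1.02) were lower. The list of inhibitory receptors and exhaustion had a median of 0.52 (1.08, above the central 95%, with the stricter filter). Of 20 measured, 8 were higher, including the orphan nuclear receptor Nr4a1 (5.46) and the inhibitory receptor Tigit (2.30). Immediate early genes had a median of 1.57, with 15 of 22 higher, such as Fos (4.92), Fosb (4.74) and Dusp1 (4.60). Heat shock genes had a median of 0.61, and 10 of 14 lay within 2-fold.

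Genes of naive T cells had a median of -0.59, with 8 of 20 at least 2-fold lower. Dapl1 stood at -3.85, the IL-7 receptor gene Il7r at -1.72 and Ccr7 at -0.78, while Tcf7 (0.22) and Lef1 (-0.49) lay within 2-fold and Myb was higher (1.92). Markers of antigen experience also split, with 6 of 20 higher and 6 lower and a median of 0.15 that turned to -0.14 under quantile normalization and to -0.06 with the median over probes: the galectins Lgals3 (4.51) and Lgals1 (3.48) and the S100 protein S100a4 (2.59) were higher, and Cd44 (-2.29), Ly6c1 (-2.18) and Il18r1 (-2.18) were lower. Costimulatory receptors had a median of -0.15, and 10 of 13 lay within 2-fold. Survival genes had a median of 0.36 that turned to -0.07 with the median over probes, and 12 of 18 lay within 2-fold. In the CD8 T cell identity list 12 of 13 genes lay within 2-fold, with a median of -0.01. The exception was the coreceptor chain Cd8b1 (-1.55), and Cd8a stood at -0.99.

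Markers of other cells differed too. Granulocyte markers had a median of 3.14 on the peptide array, which was -0.0095 and within the central 95% of random lists with the stricter filter. That filter left out members measured on 1 array alone, bright ones such as S100a9 and S100a8 among them. S100a9 was at least 1005-fold higher, and S100a8, Ltf, Ngp and Retnlg were measured on the peptide array and not on the naive one, while Mpo (-5.17) and Ctsg (-3.81) were lower. B cell markers had a median of 2.05, with Ms4a1 (4.58) higher. Markers of macrophages, monocytes and dendritic cells had a median of 0.93, with the MHC class II genes H2-Aa (4.12) and H2-Ab1 (4.10) higher. Erythroid markers had a median of 0.14 that turned to -0.08 under quantile normalization, with the globin Hba-a1 at 2.40 and Car2 measured on the naive array alone. Platelet markers had a median of -2.70 that turned to 1.25 with the stricter filter, and 8 of 9, Pf4 and Ppbp among them, were measured on the naive array alone. The stricter filter left out these 8, so 1.25 is the value of Itgb3 alone. Plasma cell markers had a median of 1.12, with Sdc1 measured on the peptide and not on the naive array (log2 bound 7.29) and Jchain at -3.27. Sdc1 was measured on the DC array too, with a bound of 7.49 over naive. CD4 and regulatory T cell markers had a median of 0.56, with Cd4 at 1.04 and Foxp3 at 0.09. Stromal markers had a median of 0.14, with 3 of 8 measured at least 2-fold higher, among them the collagen Col1a2 (9.16) and Pdgfrb (5.06). With the stricter filter the median was 5.06, above the central 95%, which equals the value of Pdgfrb.

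Among genes measured on both the peptide and the naive array, the largest positive differences were those of Syt13 (10.28, or 1246-fold), Col1a2 (9.16), the cytokine Tnfsf11 (8.24), Padi3 (8.22) and the receptor Notch3 (8.11). The largest negative ones measured on both were those of Klra16 (-7.36), Vopp1 (-6.53), Rab6b (-6.12) and Eci1 (-5.75). On the naive array Syt13 and Notch3 (scaled log2 -4.51 each) lay near the lowest well-above-background signal (-4.89), so the size of their differences is imprecise. Slide, scan and way of isolation differed between these arrays along with priming and cannot be told apart from it. With quantile normalization the median difference of all genes fell by 0.12 for peptide minus naive and by 0.15 for DC minus naive, and the counts became 1958 higher and 1602 lower for the peptide array.

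**Figure D1:**
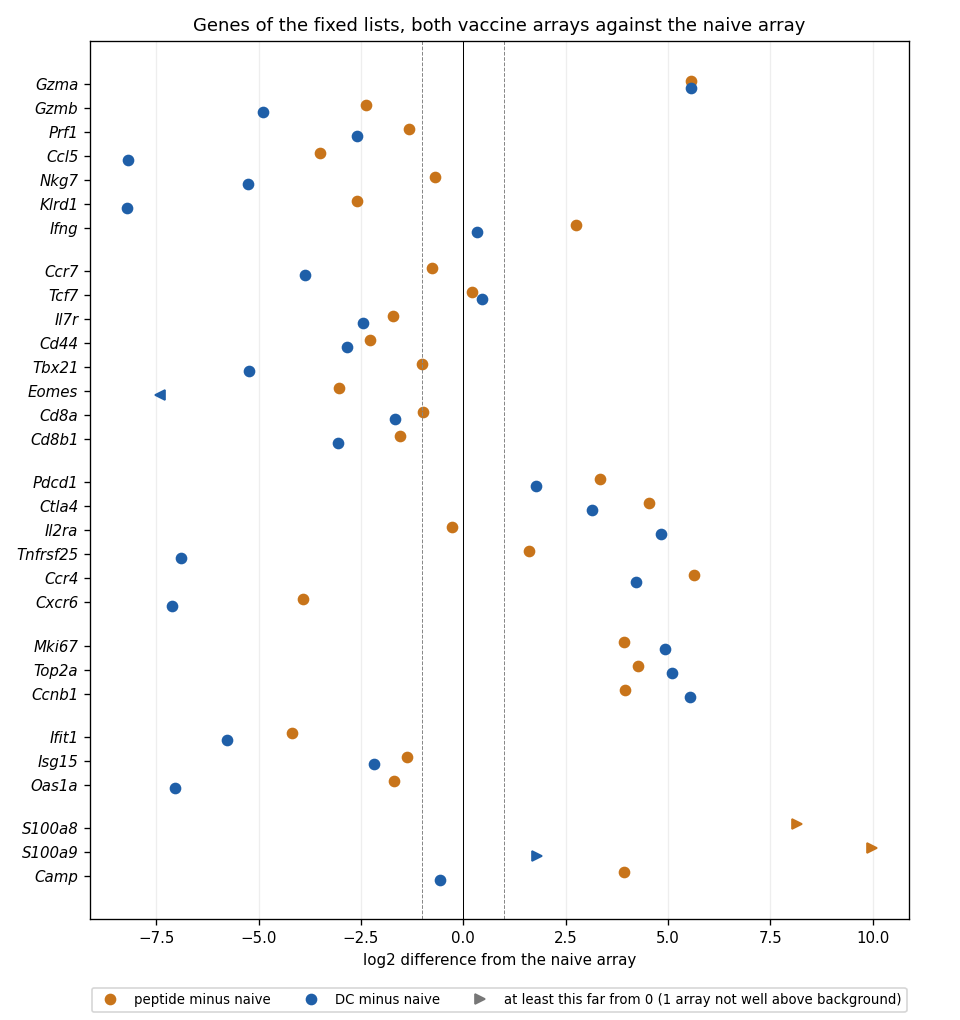
Log2 difference from the naive array for chosen members of the fixed lists. Circles are genes well above background on both arrays, and arrowheads are bounds where 1 array was not well above background. Mki67 stands at 3.92 (peptide, orange) and 4.92 (DC, blue), and Gzmb at -2.37 and -4.90; dashed lines mark 2-fold.

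In the comparison of DC-primed with naive cells, the cell cycle genes were again higher and the medians of cytotoxic, interferon-stimulated and lectin-like receptor genes lower, each farther from 0 than in the peptide comparison. Mki67 was 30.2-fold higher on the DC array, Gzmb 30.0-fold lower and Prf1 6.03-fold lower. The T-box transcription factors Tbx21 and Eomes were 37.4-fold and at least 171-fold lower. Ptcra, which encodes the pre-T cell receptor alpha chain of developing T cells, was at least 879-fold higher, and Notch3 was 478-fold higher. The fold of Notch3 is imprecise, as its naive signal lay near the lowest well-above-background signal. Of 12114 genes measured on both arrays, 2836 were at least 2-fold higher on the DC array and 1788 lower, and a further 841 and 530 were measured on the DC or the naive array alone with a bound of at least 2-fold.

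The median of the proliferation list was 4.82, and all 29 measured genes were higher, with Bub1b at 5.93, Ccnb1 at 5.55 and Cdk1 at 5.28. Glycolysis had a median of 0.99 (10 of 20 higher, 4 lower), oxidative phosphorylation 1.11 (13 of 20 higher) and cholesterol synthesis 1.19 (12 of 19 higher). Hk2 stood at 3.59, Tpi1 at 3.14, Sqle at 3.03 and Cox6c at 2.12. Fatty acid oxidation had a median of 0.57, with 7 of 17 higher, such as Acaa2 (2.07). Ribosomal protein genes all lay within 2-fold. Heat shock genes had a median of 0.53 that turned to -0.07 under quantile normalization, with Hsp90aa1 at 1.92 and Hspd1 at 1.79.

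All 26 measured interferon-stimulated genes were lower on the DC array, 25 of them at least 2-fold on both arrays and Ifi44 by its bound, and the median was -3.25. Ifit3 stood at -7.21, Oas1a at -7.04, Ifi27l2a at -5.87 and Irf7 at -4.13. Of 17 measured lectin-like receptors, 15 were measured on the naive and not on the DC array, and Klrd1, measured on both arrays, stood at -8.21. Some of the 15, such as Klrg1 and Klrc1, were also measured on the peptide array. NK cell markers had a median of -3.87, with the adaptors Tyrobp and Fcer1g at -4.30 and -3.92. Cytotoxic molecules had a median of -2.58, with Nkg7 at -5.25 and Ctsw at -5.17, and Gzma was again higher (5.57). Cytokines and chemokines had a median of -1.79. Ccl5 was 291-fold lower, Ifng stood at 0.33, and Il10 was measured on the DC array alone, with a log2 bound of 5.14. Chemokine receptor and trafficking genes had a median of -3.02, and Ccr4 (4.21) was the 1 member of 20 at least 2-fold higher.

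Genes of naive T cells were at least 2-fold lower for 11 of 20 members, with a median of -1.75: Dapl1 stood at -7.30, the migration receptor S1pr1 at -4.26, Bach2 at -4.18 and Ccr7 at -3.87, while Tcf7 (0.46) and Lef1 (0.09) lay within 2-fold and Myb was higher (2.49). Markers of antigen experience had a median of -2.41, with Il18r1 (at least 321-fold), Ahnak (-3.76), S100a10 (-3.69) and Cd44 (-2.85) lower and Anxa2 (3.19) higher. Effector and memory transcription factors had a median of -0.90 (-0.60, within the central 95%, with the stricter filter), with Hopx at -6.62 and, on the higher side, Nfil3 at 3.10 and Irf4 at 3.02. The list of inhibitory receptors and exhaustion had a median of -0.02 that turned to 0.06 with normexp and 0.05 with the median over probes. Nr4a1 (4.54), Ctla4 (3.13) and Pdcd1 (1.78) were higher. Nt5e was measured on the naive and peptide arrays and not on the DC array, with a log2 bound of -7.01 for DC minus naive. Costimulatory receptors had a median of -1.65, with 8 of 13 lower, such as the death receptor family member Tnfrsf25 (-6.89), Cd226 (-5.72) and Cd69 (-4.28). The IL-2 receptor alpha chain gene Il2ra was the 1 higher member (4.83, or 28.4-fold). Immediate early genes had a median of -0.27, which lay below the central 95% without the filter and with the median over probes, as did -0.34 with normexp and -0.78 under quantile normalization, with Fos (4.34) and Dusp1 (3.31) higher and Fosl2 (-1.92) lower. Survival genes had a median of -0.63, with Bcl2a1d at -5.92 and Bcl2 at -2.80.

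Among CD8 T cell identity genes 4 of 13 were at least 2-fold lower on the DC array, among them Cd8b1 (-3.05), Cd8a (-1.67) and Cd5 (-1.06), and Cd3d (-0.07), Cd3e (-0.06) and Cd3g (0.15) lay within 2-fold. The list median of -0.07 lay below the central 95% of random lists (-0.02 to 1.14), and within it with the median over probes. Platelet markers had a median of -2.77 and erythroid markers of -2.53, with Pf4 and Ppbp measured on the naive array alone and Hba-a1 at -3.21. Granulocyte markers had a median of -0.35 that turned to 0.25 without the filter, and B cell markers of -0.66, where the marker Ms4a1 (0.02) lay within 2-fold. The B cell list split: of 13 measured, 4 were at least 2-fold higher, such as Vpreb3 (3.15) and Blnk (2.33), and 4 lower, such as Cd72 (-5.86) and Cr2 (-2.39). Macrophage, monocyte and dendritic cell markers had a median of 0.01 that turned to -0.02 under quantile normalization and to -0.05 with scaling on probes measured on all arrays, with H2-Ab1 at 4.69. Plasma cell markers had a median of 0.69, CD4 and regulatory T cell markers of 0.02 that turned to -0.07 and -0.04 with the same alternatives and to -0.18 with the median over probes, and stromal markers of 0.13, or 5.93, above the central 95%, with the stricter filter. Cd4 stood at 1.12. Of 9 measured stromal markers, 2 were at least 2-fold higher on both arrays and 1 by its bound. Col1a2 stood at 6.99 and Pdgfrb at 5.93, which equals the stromal median with the stricter filter.

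The largest positive differences measured on both arrays were those of Syt13 (10.64), Fam183b (8.91), Notch3 (8.90), Tmem151b (7.94) and Ptpro (7.81), and Uaca and Mpzl2 were at least 2325-fold and 681-fold higher. The largest negative ones were those of the cyclin Ccnd2 (-9.35), the neuropeptide receptor Vipr1 (-8.34), Klrd1 and Ccl5, and Samhd1 was at least 1007-fold lower. The values of Syt13 and Notch3 again rest on naive signals near the lowest well-above-background signal. As for the peptide array, slide, scan and isolation cannot be told apart from priming here. With quantile normalization the counts became 2372 higher and 2105 lower.

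The comparisons of either vaccine with naive cells use the same naive array. Among 11873 genes measured on all 3 arrays, 1817 were at least 2-fold higher on both vaccine arrays than on the naive array, and 988 were at least 2-fold lower on both. Independent lists of the same sizes would share 509 and 182 genes. Unchanged arrays simulated with a noise SD of 0.353 per array against a shared naive array gave 47.7 and 48.0 genes. That SD was assumed from the spread of DC minus peptide over these genes, which also holds real differences between the vaccines. The peptide and DC arrays shared a slide and scan, so noise from the naive array's own slide and isolation is missing from the simulation. The excess over the simulated counts may therefore be overstated. Across genes, which are not independent replicates, the 2 differences had a Pearson correlation of 0.847 and a covariance of 1.66, against 0.501 and 0.125 for simulated unchanged arrays. The single naive array cannot be split, so part of the excess can come from it. In the opposite direction, 38 genes were at least 2-fold higher on the peptide array and lower on the DC array, and 5 the reverse.

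**Figure D2:**
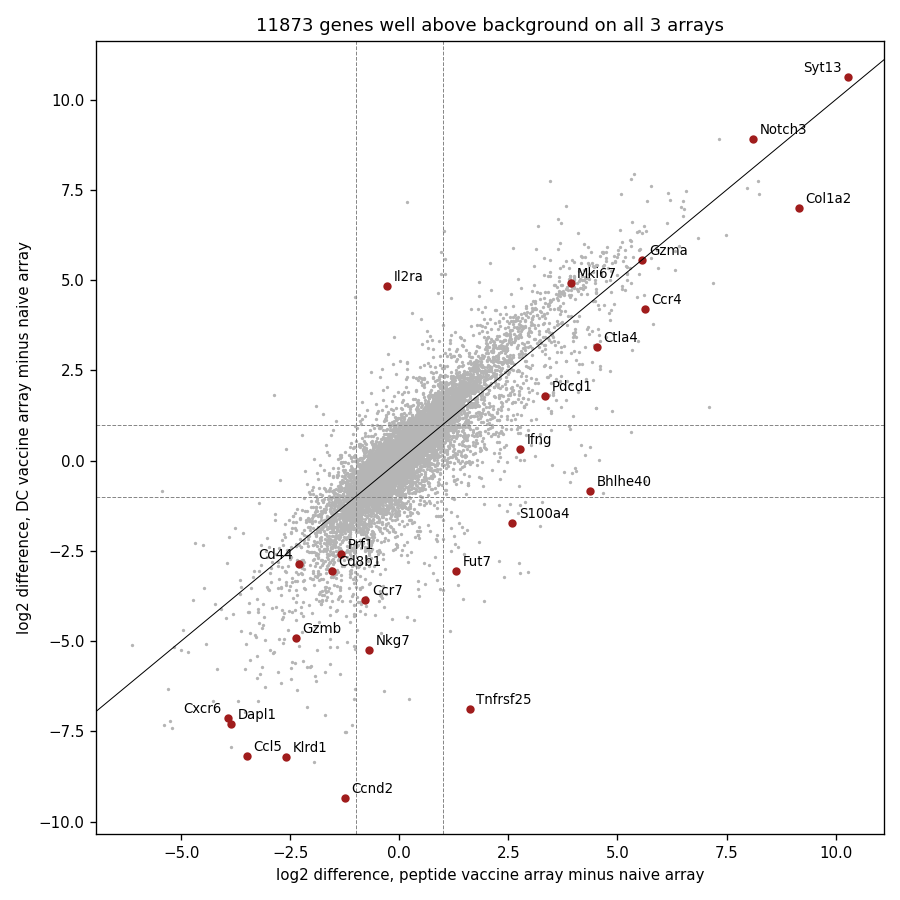
Log2 difference from the naive array on the peptide vaccine array (horizontal axis) and on the DC vaccine array (vertical axis) for 11873 genes well above background on all 3 arrays. Each point is a gene, the solid line marks equal differences, dashed lines mark 2-fold, and red points carry gene names; 1817 genes lie beyond 2-fold at the upper right and 988 at the lower left, while Tnfrsf25 lies at 1.61 and -6.89.

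Between the vaccines, 3 lists had lower medians on the DC than on the peptide array: cytotoxic molecules, chemokine receptors and trafficking, and inhibitory receptors and exhaustion. Other lists did too, as given below, and the cell cycle list had a higher one. Ptcra was 305-fold higher on the DC array and Il2ra 34.4-fold higher. The fold of Ptcra is imprecise, as it was dim on the peptide array (scaled log2 -3.36, with a lowest well-above-background signal of -4.32). Tbx21 was 18.5-fold lower, Eomes at least 20.7-fold lower, Gzmb 5.79-fold lower and Ifng 5.42-fold lower. Tnfrsf25 was 362-fold lower, and the calprotectin gene S100a9 was 288-fold lower. Of 12387 genes measured on both arrays, 784 were at least 2-fold higher on the DC array and 1007 lower, and a further 305 and 412 were measured on the DC or the peptide array alone with a bound of at least 2-fold. These arrays shared a slide and a scan.

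Proliferation genes had a median of 0.94, with 12 of 29 at least 2-fold higher on the DC array and none lower by as much, and Ccnb1 (1.60) and Plk1 (1.28) among the higher ones. The metabolic lists lay closer together, with medians of 0.13 for glycolysis, 0.18 for cholesterol synthesis and 0.25 for fatty acid oxidation (0.51, above the central 95%, with the stricter filter). Oxidative phosphorylation had a median of 0.29, above the central 95% of random lists (-0.07 to 0.27), although all 20 of its genes lay within 2-fold. Ribosomal protein genes had a median of 0.05, which turned to -0.015 under quantile normalization, and heat shock genes of -0.14, which lay within the central 95% without the filter. Interferon-stimulated genes had a median of -1.21, with 13 of 25 lower: Oas1a stood at -5.35, Ifi27l2a at -4.16 and Oas2 at -3.67.

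Cytotoxic molecules had a median of -1.47, with Nkg7 at -4.55 and Ctsw at -3.75, and Gzma stood at 0.00. Cytokines and chemokines had a median of -2.03, with Ccl5 at -4.69 and Ltb at -2.40, and Il10 was measured on the DC array alone. Chemokine receptor and trafficking genes had a median of -1.84, with the fucosyltransferase Fut7 at -4.38, the integrin Itgb7 at -3.31 and the receptor Cxcr6 at -3.20. Effector and memory transcription factors had a median of -1.30, with Hopx (-5.57), Bhlhe40 (-5.22) and Rora (-3.52) lower and none of 18 at least 2-fold higher. The list of inhibitory receptors and exhaustion had a median of -1.40, with 10 of 18 lower, such as the nuclear receptor Nr4a2 (-2.28) and the inhibitory receptors Tigit (-1.98) and Pdcd1 (-1.56). Costimulatory receptors had a median of -1.47, with Cd69 (-3.73) and Cd226 (-3.66) lower. Immediate early genes had a median of -1.52, with 16 of 22 lower, such as Gadd45b (-3.86) and Fosl2 (-3.46). Naive T cell genes had a median of -0.59, with Igfbp4 (-3.89), S1pr1 (-3.23) and Ccr7 (-3.09) lower. Markers of antigen experience had a median of -1.40, with S100a6 at -4.59 and S100a4 at -4.31. Lectin-like receptors had a median of -0.97 over 9 measured members, survival genes of -0.48, and CD8 T cell identity genes of -0.16.

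Of the lists of markers of other cells, those of stromal cells and platelets had medians within the central 95% of random lists, and the others had medians below it. Granulocyte markers had a median of -3.24, with S100a8, Ltf, Ngp and Retnlg not well above background on the DC array and Camp at -4.49. All 15 measured B cell markers were at least 2-fold lower or, for 3, measured on the peptide array alone, among them Ms4a1 (-4.56). Macrophage, monocyte and dendritic cell markers had a median of -1.19, with Cd74 at -2.83, and erythroid markers of -0.81, with Hba-a1 at -5.61. NK cell markers had a median of -2.09, plasma cell markers of -0.71 (-0.23, within the central 95%, without the filter), CD4 and regulatory T cell markers of -0.87 (-0.26 with normexp and -0.35 without the filter, both within the central 95%), stromal markers of -0.31, and platelet markers, with 2 measured, of -1.38, which turned to 0.018 without the filter and was -1.53 with normexp and -3.35 with the stricter filter, both below the central 95%. The -3.35 is the value of Itgb3 alone. Other large differences measured on both arrays were those of Iftap (6.99), Foxb1 (6.29), Uaca (5.56) and Ace (5.56) on the higher side, and Ccnd2 (-8.10), Rarg (-6.84), Vipr1 (-6.39) and the cytokine-signalling inhibitor Cish (-5.89) on the lower side. Exoc3l4 was at least 135-fold higher, and Samhd1 at least 87.9-fold lower. With normexp, 469 genes in place of 784 were at least 2-fold higher, and with the stricter filter on dim probes 514.

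**Figure D3:**
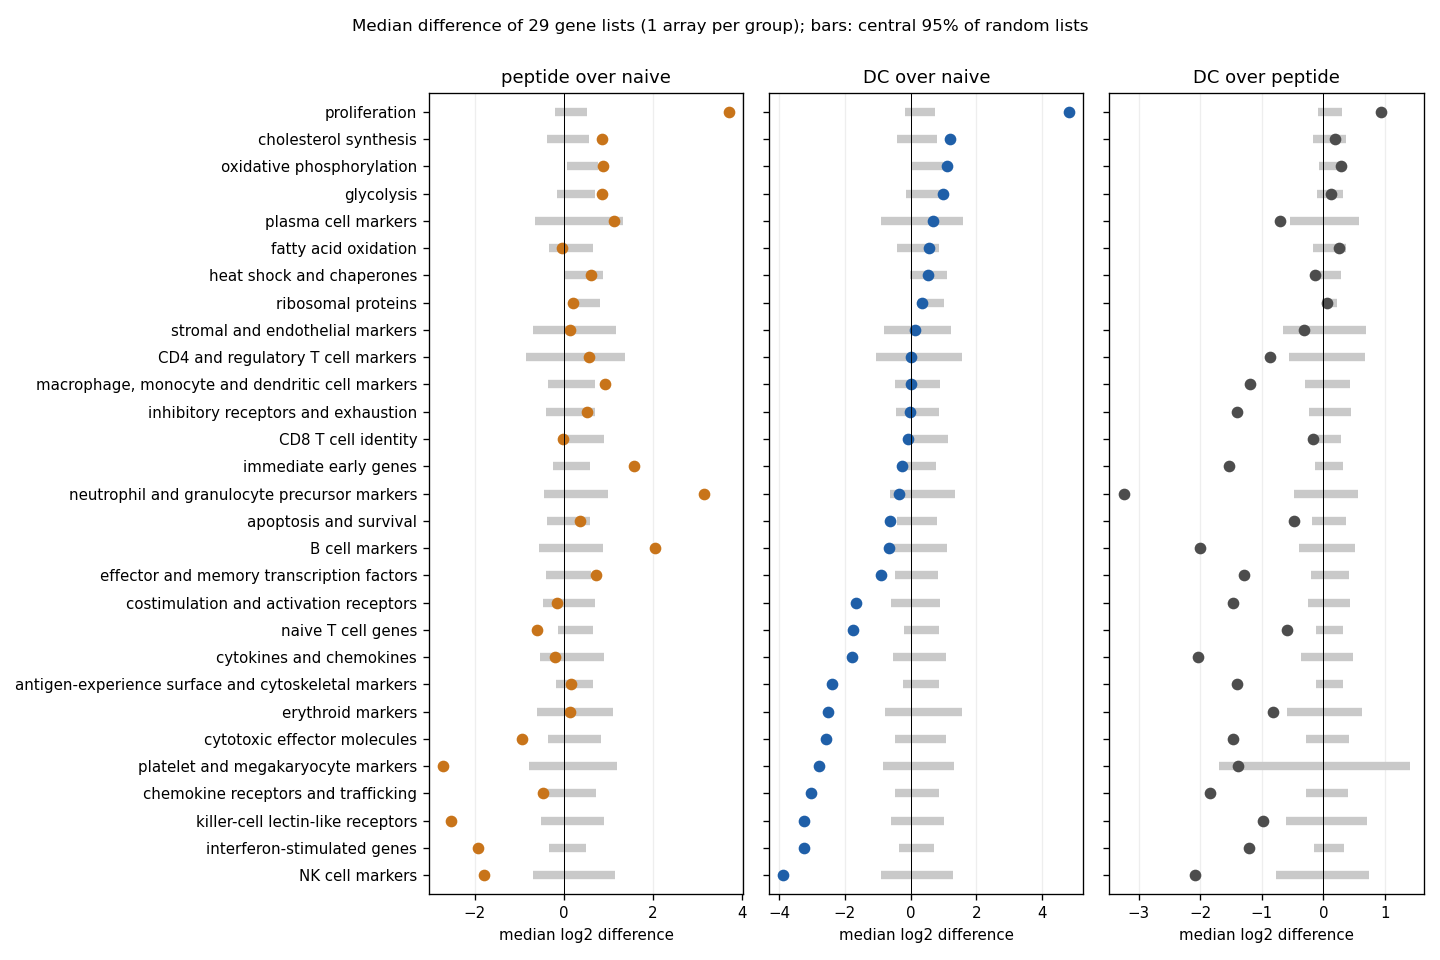
Median log2 difference of each of the 29 gene lists (points) in the 3 comparisons, beside the central 95% of matched random lists (grey bars). The proliferation list lies at 3.70, 4.82 and 0.94 and the interferon-stimulated list at -1.93, -3.25 and -1.21 for peptide over naive, DC over naive and DC over peptide.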

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

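The genes and the list below were picked because the peptide and DC arrays differed from the naive array in opposite directions, each by at least 2-fold among list members, or, for a whole list, on opposite sides of the central 95% of random lists; with 1 array each, the difference between the vaccines was not tested. The tests on granulocyte and NK cell markers and on exchanged arrays were chosen after the result was seen, as was the bootstrap range of the mixture test.

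In each case the peptide array was above and the DC array below the naive array. For DC minus peptide, the largest such difference was that of Tnfrsf25 (-8.50). The globins Hba-a1 and Hba-a2 stood at -5.61 and -5.08, and the S100 proteins S100a6 and S100a4 at -4.59 and -4.31. The fucosyltransferase Fut7 stood at -4.38, the integrin Itgb3 at -3.35 and the complement receptor Cr2 at -3.75. The chemokine receptor Ccr6, not well above background on the DC array, had a bound of -3.50. Stress and immediate early genes were Gadd45b (-3.86), Fosl2 (-3.46), Gadd45g (-3.15), Pmaip1 (-2.86), Ier3 (-2.43) and Egr1 (-2.23). The transcription factor Rora stood at -3.52 and the lysozyme Lyz1 at -3.48. The list of effector and memory transcription factors had a DC minus peptide median of -1.30; with the stricter filter its DC minus naive median of -0.90 became -0.60, within the central 95%.

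Part of the granulocyte list was higher on the peptide array than on both others. Of 14 measured members for peptide minus naive, 8 (S100a8, S100a9, Camp, Ngp, Ltf, Retnlg, Lcn2 and Chil3) were at least 2-fold higher on the peptide array than on the naive and on the DC array, whereas Mpo (-5.17) and Ctsg (-3.81) were lower than on the naive array, Prtn3 and Cxcr2 were measured on the naive array alone, and Csf3r and Elane lay within 2-fold. S100a9 reached 5.09 and S100a8 3.27 on that array's scaled log2 axis. Granulocyte RNA in the peptide sample may account for these 8 genes, although the labels describe a sort for pmel-1 CD8+ T cells, which would leave granulocytes out. For T cell genes such as Tnfrsf25 and Rora no explanation was tested.

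The lists of cytotoxic molecules, lectin-like receptors and interferon-stimulated genes had medians below the central 95% of random lists on both vaccine arrays, although Gzma was higher on both and the lectin-like receptors, peptide over naive, lay within the central 95% with the stricter filter (-2.06). That filter left out the 8 lectin-like receptors measured on the naive array and not on the peptide array. An exchange of the naive and DC arrays is argued against by the genes of naive T cells, whose median was -1.75 for the array labelled DC. A peptide array that was only a mixture of the other 2 profiles would hold 1 constant share of the naive signal; over the 211 genes measured on the naive and peptide arrays and at least 16-fold lower on the DC array than on the naive array, the 90th over the 10th percentile of that share was 13.0 (8.28 to 19.8 over 1000 bootstrap draws of genes). NK cells in the magnetically separated naive sample may have raised the lectin-like receptors and part of the cytotoxic genes there, since 7 of 9 NK cell markers, 2 of them also in the lectin-like receptor list, were at least 2-fold higher on the naive array than on both others, with Klra4 at 2.72 on its scaled log2 axis, whereas Khdc1a went the other way, with bounds of 5.47 (peptide) and 3.08 (DC) over naive, and Cd244a lay within 2-fold. As 0 slides held both naive and vaccine arrays, slide and scan cannot be told apart from priming, and priming itself stays open as an untested biological difference. Genes of immature T cells on the DC array and sex-linked genes on both vaccine arrays also differed from the naive array, as described below. Whether either bears on these lists was not tested.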

How the results depend on the processing

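No paired analysis was possible because each group has 1 array, and for the same reason no replicate was left out; no spot was saturated, so that alternative moves nothing and was not run. With scaling on probes measured on all arrays and with the deposited processed values, all 98 counts and list medians stayed within 1.5 times (counts) or on their side of the central 95% of random lists (medians), and so did all 87 list medians with measured differences in place of bounds, an alternative chosen after seeing the data. Of the list medians, 2 turned sign with the first of these (CD4, -0.038, and macrophage genes, -0.047, both DC over naive and within the central 95%) and 0 with the others, against 9 with quantile normalization, 1 with normexp, 4 with the median over probes, 2 without the filter and 3 with the strict filter. Of 901 values of named genes, none at least 2-fold apart turned sign with scaling on probes measured on all arrays or with the deposited values. Smaller differences were not checked for sign. With these, 901 and 857 moved by no more than the 95% half-width for a probe of median spread, and with normexp 599 moved by more. That half-width is too narrow for dim probes. The agreement was largely fixed in advance. That scaling shifts every difference of a comparison by 1 constant (-0.039, -0.055 and -0.016), and the deposited values hold nearly the same differences as the main values. In the following cases the cause was not tested, except that leaving the filter out or tightening it changes the genes counted. Without the filter, counts of genes at least 2-fold higher and lower were 3852 and 2303 (peptide over naive), 4794 and 2972 (DC over naive) and 1831 and 2051 (DC over peptide), and 2788 and 1814 were shared by both vaccine arrays; normexp gave 446, 660 and 203 genes measured on 1 side and 469 higher for DC over peptide, and the strict filter gave 514. List medians that crossed the bounds of random lists without the filter were ribosomal proteins (0.20, peptide over naive), immediate early genes (-0.27, DC over naive), and heat shock (-0.14), plasma cell (-0.23) and CD4 (-0.35) genes for DC over peptide. With the strict filter these were, for peptide over naive, cytokines (-1.35), lectin-like receptors (-2.06), inhibitory receptors and exhaustion (1.08), NK cells (-1.41), granulocytes (-0.0095) and stroma (5.06), and platelet genes turned sign (1.25). For DC over naive they were transcription factors (-0.60) and stroma (5.93). For DC over peptide they were fatty acid oxidation (0.51), plasma cells (-0.23), CD4 (-0.65) and platelets (-3.35). With quantile normalization they were ribosomal proteins (-0.052, peptide over naive) and immediate early genes (-0.78, DC over naive); with normexp immediate early genes (-0.34, DC over naive), CD4 (-0.26) and platelets (-1.53, both DC over peptide); with the median over probes CD8 identity (-0.069) and immediate early genes (-0.27), both DC over naive. Ahnak, DC over peptide, turned sign with the median over probes (0.0069). With the strict filter, which leaves out genes measured on 1 array of a pair, both platelet values were those of Itgb3 alone. The stromal values with it equalled those of Pdgfrb. The interferon list, DC over naive, kept its direction in all of these alternatives, and its median nearest to 0 was -2.72, with normexp, a background correction. This test of scaling between arrays was set before its result was seen. Quantile normalization and scaling on probes measured on all arrays shifted the median of all genes by only -0.15 and -0.055. They could hardly have brought the list's -3.25 near 0. The test shows that these scalings do not account for its lower values, and says nothing of others. Signal over background limits the genes measured on 1 side, for which only bounds are given.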

Other observations

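The lists of thymocyte and Notch target genes were drawn up after Ptcra, Notch3 and Il2ra had been seen and without these 3 genes, and before the values of their own members were looked at, apart from Cd3d, which also stands in the list of CD8 T cell identity. The list of Y-linked genes and its test were chosen after the result was seen.

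Genes that developing T cells use to rearrange their receptor were high on the DC array. The recombinase genes Rag1 and Rag2 were measured on the DC array and not on the naive array, with log2 bounds of 9.13 and 4.89, and Dntt, which encodes terminal transferase, stood at 3.43 for DC minus naive. Arpp21 (5.63) and Cd24a (5.84) were higher as well, whereas Bcl11a and Hhex were measured on the naive array and not on the DC array, and Lyl1 was lower (-2.43). On the peptide array, Cd24a (5.90) and Arpp21 (3.32) were also higher than on the naive array, Rag1 had a bound of 4.59, Dntt stood at -0.12 and Rag2 was not well above background. For DC minus peptide, Rag1 stood at 4.54 and Dntt at 3.56. The Notch targets Hes1 and Heyl were measured on both vaccine arrays and not on the naive array, with bounds over naive of 7.85 for Hes1 on the peptide array and 6.11 for Heyl on the DC array, and Nrarp stood at 2.98 for DC minus naive. Other members went the other way: Hes5 was measured on the naive and not on the DC array, Hey1 stood at -0.94 for DC minus naive and -2.46 for DC minus peptide, and for peptide minus naive Nrarp had a bound of -1.15 and Notch1 stood at -1.04.

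Together with Ptcra, Notch3 and Il2ra, these values suggest as a hypothesis that the sample on the DC array held cells with a program of immature T cells. The median of the 15 measured thymocyte genes for DC minus naive was 1.12, at percentile 98.7 of random lists, which describes these arrays and is no test between groups, with the bound for it set before it was seen. For peptide minus naive it was 0.35, at percentile 72.3, and for DC minus peptide 0.13, at percentile 55.3. The Notch target list, with 7 genes and a median of 0.87, lay at percentile 86.2 for DC minus naive, which decides nothing, at 84.2 for peptide minus naive (0.74) and at 99.9 for DC minus peptide (1.15). Of the 18 thymocyte genes, 13 were also well above background on the naive array, so the list is not specific to thymocytes, and the labels give spleen as the tissue and a sort for pmel-1 CD8+ T cells. Whether such cells came with the sort, from another sample or from the primed cells themselves was not tested.

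Sex-linked genes also separated the naive array from the vaccine arrays. Xist, which is expressed from the inactive X chromosome, was well above background on the naive array (1.41 on the scaled log2 axis) and not on the others. The Y-linked genes Ddx3y, Eif2s3y and Uty were well above background on the peptide and DC arrays and not on the naive array, with Eif2s3y at 3.18 and 3.14, and Kdm5d was not well above background on any. The median of the 3 measured Y-linked genes was at least 7.54 for peptide minus naive and at least 6.95 for DC minus naive, where every value is a bound. For DC minus peptide it was -0.40. Cells from mice of different sex are a candidate explanation for these 3 genes and Xist, and any such difference goes together with priming and slide.

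The granulocyte markers Csf3r (-0.15 for peptide minus naive and -0.13 for DC minus naive) and Elane (-0.0095 and -0.06) had nearly equal signals on all 3 arrays, while Mpo was lower on both vaccine arrays (-5.17 each).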
